A study of Mus musculus with 6 samples.

How the data were processed

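The deposited table gave 1 value per gene and library for 21436 mouse genes (16207 protein-coding and 5229 non-coding) in 6 libraries, 3 of 3T3-L1 cells alone and 3 of 3T3-L1 cells cultured below human umbilical cord mesenchymal stem cells. The values are FPKM, fragments per kilobase of gene scaled to the library total, as deposited by the authors. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 kit. The submitters' processing notes name fastp, HISAT2, HTSeq and the mm10 genome, without versions or settings. The annotation version and whether counting used strand are not given in the sources used here, so genes that overlap others, or that have near-identical copies, are uncertain. With a mouse reference, how reads of the human cells would have been treated is also not given in the sources used here. All 6 value columns were matched to samples by name, and 0 value columns were left without a sample.

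Depth was recovered from the values. The ratios between libraries of a gene's low FPKM values are those of whole read numbers divided by library totals, and all 21436 genes resolved to whole reads (tolerance 1e-06 on the ratios). The scale was set with the 1545 bp of the mitochondrial gene for cytochrome c oxidase subunit 1. Of the 12045 genes with at least 100 reads, 99.2% then had a whole-number length within 0.001 bp, and 100% after 419 genes were multiplied by a common factor. The library totals that the authors divided by were 37929978, 36119750 and 38357563 for alone replicates 1 to 3, and 29603755, 37612585 and 37325449 for co-culture replicates 1 to 3. The listed genes held 98.6% to 98.7% of them. Floors of 3 reads cover counting error only, since reads without molecular identifiers are not independent molecules.

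The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2(FPKM + 1), co-culture minus alone, without a replicate block. It was run on the 10055 genes with a mean of at least 1 FPKM over the 6 libraries, and 11381 genes were not tested. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called, and a second count took those with an absolute log2 change of at least 1. Pparg, Cebpa, Adipoq and Plin1 were below the filter, and their adjusted p come from the fit without it. The fit was tested on simulated reads for the same 10055 genes. It recovered 71.6% of 1.25-fold, 97.0% of 1.5-fold and 100% of 2-fold changes, 6.77% of its 192 calls were unchanged genes, and it made 0 calls in 5 runs with no change. Principal components and Pearson correlations described the spread of the libraries.

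Before the data were examined, the tests, the alternatives, the naming rule and 27 gene lists were fixed. The lists were adipocyte identity, adipogenic transcription factors, anti-adipogenic regulators, fatty acid and triglyceride synthesis, lipolysis and fatty acid oxidation, thermogenic adipocyte, cholesterol synthesis, proliferation, extracellular matrix, TGF-beta and contractile, inflammatory NF-kB, interferon response, Wnt beta-catenin targets, hypoxia and glycolysis, oxidative phosphorylation, unfolded protein and integrated stress response, glucocorticoid targets, cyclic AMP targets, insulin signalling, oxidative stress NRF2 targets, apoptosis and p53 targets, and markers of macrophages, endothelium, epithelium, muscle, bone and cartilage, and mesenchymal stromal cells. The 21 lists with at least 5 tested members were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists), beside camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way. Terms of GO, KEGG, WikiPathways and Reactome in the deposited table with 10 to 300 tested genes were tested in the same way with camera. The genes named were the 12 largest rises and 12 largest falls among called genes whose groups did not overlap (leaving out predicted and clone-based symbols), up to 4 called members of each list by smallest p, and Pparg, Cebpa, Cebpb, Cebpd, Fabp4, Adipoq, Plin1, Lpl and Dlk1. For lists of other cell types the 2 members with the highest mean were added. A gene that this rule selects is not reported here. A few further list members are given as examples chosen after their values were seen: Hspa5, Ndrg1, Pfkfb4 and C3.

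The alternatives were pseudocounts of 0.1 and 0.01, no filter and a filter at a mean of 5 FPKM, median-ratio, TPM and quantile scaling, eBayes without a trend, array weights, the replicate number as a block, each library left out in turn, and an adjusted p threshold of 0.01. Alternatives added after the data were seen were limma-voom on the recovered reads, a correction of each library for GC content and gene length with splines of 5 degrees of freedom (97.8% of tested genes had both values), and counts of list members without each library. All alternatives for the spread of the libraries were also added then. Coordinates are those of RefSeq on GRCm38.p6, the assembly behind mm10, matched by the Entrez identifiers in the deposited table. Figures were drawn with matplotlib 3.10.9.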

Results

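Gene expression was measured by RNA sequencing in mouse 3T3-L1 preadipocytes, an embryonic fibroblast line that turns into adipocytes under hormonal induction. The cells were grown in the lower chamber of a Transwell with a 0.4 µm membrane and kept for 72 h in a medium that induces adipocyte differentiation. That medium held 2 µM rosiglitazone (a PPARγ agonist), 1 µM dexamethasone (a glucocorticoid), 0.5 mM IBMX (a phosphodiesterase inhibitor that raises cyclic AMP), 10 mg/L insulin and 10% serum. The upper chamber was either empty (alone, 3 libraries) or held human umbilical cord mesenchymal stem cells (co-culture, 3 libraries). The question was how the human cells, separated by the membrane, altered expression in the preadipocytes. The library totals recovered from the deposited values were 37929978, 36119750 and 38357563 reads for alone replicates 1 to 3, and 29603755, 37612585 and 37325449 reads for co-culture replicates 1 to 3. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

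The 6 libraries separated by group. The first principal component of the 10055 tested genes held 68.4% of the variance and placed the 3 co-culture libraries on one side and the 3 alone libraries on the other, and the second component held 10.7%. Pearson correlations across genes were 0.9974 to 0.9982 between libraries of the same group and 0.9914 to 0.9928 between groups, where genes are not independent replicates. Alone replicate 1 stood somewhat apart within its group. Its mean chi-square per gene was 10.9 against alone replicate 2 and 14.1 against alone replicate 3, while the other pairs of the same group had 3.65 to 5.39, so no pair looked like copies of 1 library. Transcripts of the mitochondrial genome took 4.56 ± 0.117% of reads alone and 4.995 ± 0.0981% in co-culture (SD, n = 3). The ranges did not overlap, and the two-sided exact permutation p of 0.1 was the smallest that 3 libraries against 3 can give.

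A small set of genes was much lower in co-culture, while most other changes were small. Lif, a cytokine of the interleukin-6 family, had the largest fall on the log2(FPKM + 1) scale, from 13.99 ± 0.0991 to 1.27 ± 0.125 FPKM (11.04-fold lower, log2 change −2.73, SE 0.0555, adjusted p = 7.27e-10). Fgf21, a metabolic hormone, was 10.4-fold lower, from 4.45 ± 0.871 to 0.427 ± 0.0787 FPKM. Il6 was 3.97-fold lower (32.5 ± 3.14 to 8.20 ± 1.252 FPKM) and Csf3, the granulocyte colony-stimulating factor, was 4.55-fold lower (17.01 ± 0.870 to 3.74 ± 0.246 FPKM). Zfp36, which encodes an RNA-binding protein that destabilises cytokine mRNAs, was 4.46-fold lower (69.7 ± 3.16 to 15.6 ± 1.85 FPKM, adjusted p = 3.75e-08).

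The rest of the 12 largest falls were Ptgs2, the inducible cyclooxygenase (3.60-fold lower, 60.1 ± 3.44 to 16.7 ± 1.45 FPKM), Socs3, a feedback inhibitor of cytokine signalling (3.73-fold lower), Ostn (4.66-fold), Ier3 (3.41-fold), Stc1 (3.30-fold), the epidermal growth factor receptor ligand Ereg (3.08-fold) and Fos (2.95-fold). On the log2(FPKM + 1) scale the largest rise was that of Carmn, a long non-coding RNA of smooth muscle cells, from 6.73 ± 0.884 to 19.3 ± 0.627 FPKM (2.86-fold higher, log2 change 1.395, SE 0.0720, adjusted p = 8.45e-07). The zinc-finger factors Klf6 (1.88-fold higher, 25.2 ± 1.23 to 47.4 ± 2.64 FPKM), Klf2 (2.64-fold) and Egr3 (1.85-fold) rose, as did the phosphatase gene Dusp5 (2.00-fold), Ppp1r10 (1.70-fold), Zfc3h1 (1.83-fold) and Fcor (2.46-fold). The remaining 4 of the 12 largest rises were the histone genes H1f5 (3.69-fold) and H4c9 (1.87-fold), Apol8 (3.67-fold) and Ly6f (2.04-fold), which belong to families of similar genes whose reads the counting could have divided. Fold changes quoted as such are ratios of mean FPKM, and log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

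In mm10 coordinates, counted from 1, Lif lies on chromosome 11 from 4257568 to 4272514, Il6 on chromosome 5 from 30013114 to 30019975, and Csf3 on chromosome 11 from 98700183 to 98703631. Zfp36 lies on chromosome 7 from 28376784 to 28379228, Fgf21 on chromosome 7 from 45613890 to 45615490, Ptgs2 on chromosome 1 from 150100031 to 150108234, and Carmn on chromosome 18 from 61645878 to 61665538. Lpl lies on chromosome 8 from 68880555 to 68906932, Fabp4 on chromosome 3 from 10204342 to 10208616, and Pparg on chromosome 6 from 115360879 to 115490404.

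**Figure D1:**
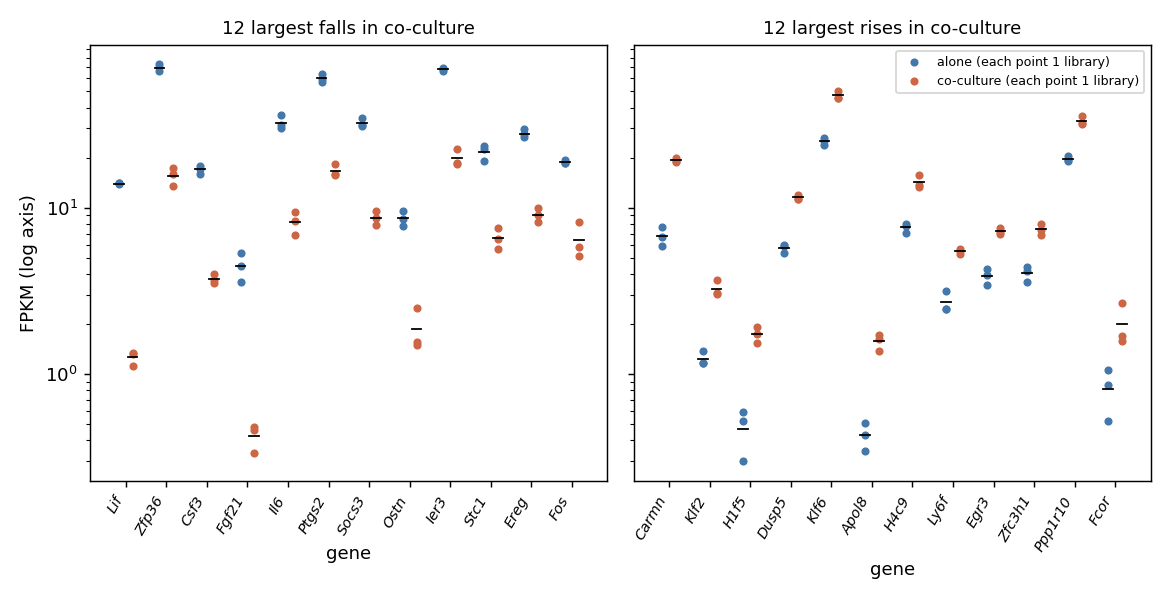
FPKM (log axis) of the 12 genes with the largest falls and the 12 with the largest rises in co-culture; each point is 1 library (3 alone, 3 co-culture) and each bar is a group mean. The groups do not overlap for any of the 24 genes, and Lif falls from a mean of 13.99 to 1.27 FPKM.

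In all, 3201 of the 10055 tested genes differed between the groups (limma with Benjamini-Hochberg adjustment), 1402 higher (13.9%) and 1799 lower (17.9%) in co-culture. Of the 26 that changed by a log2 of at least 1, Carmn was higher and 25 were lower. These counts depended on the setting, with 8 higher and 32 lower at a pseudocount of 0.1, 11 and 33 at 0.01, 4 and 34 with TPM scaling, and 10 and 35 with limma-voom on the recovered reads. The median size of the 3201 changes was 0.23 on the log2 scale, and 2984 of them (93.2%) were below 0.5. The groups did not overlap for 4637 genes (46.1%), against 10% by chance. The number of genes called higher was 925 without co-culture replicate 3. Hbb-bs, a globin gene chosen after its values were seen, was among the 25 and had 0 reads in co-culture replicate 1. Over 12 globin and neutrophil genes there were 392, 381 and 782 reads in alone replicates 1 to 3 and 9, 195 and 344 in co-culture replicates 1 to 3.

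**Figure D2:**
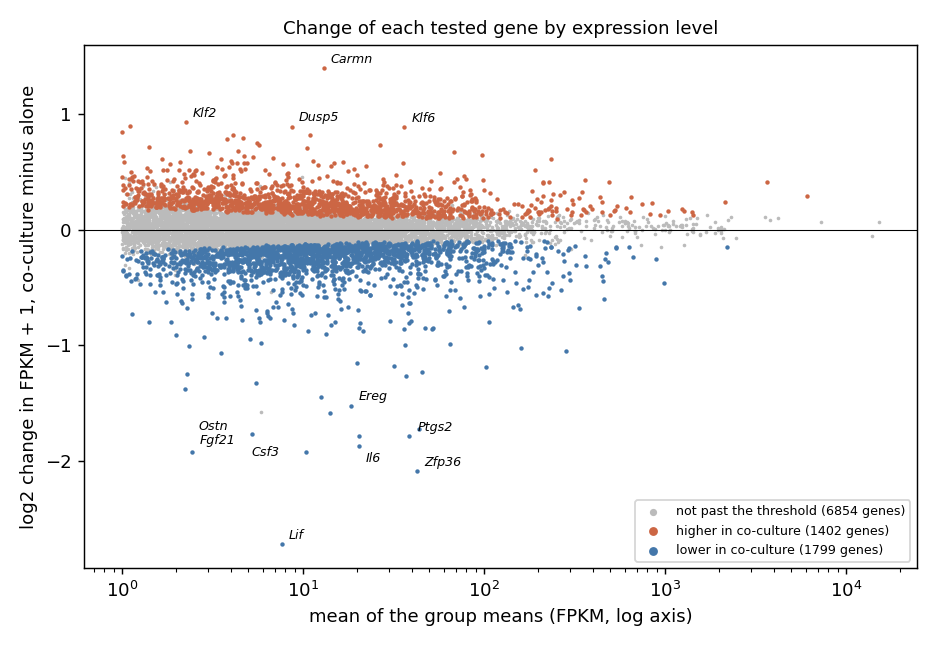
The log2 change in FPKM + 1 (co-culture minus alone) of each of the 10055 tested genes against the mean of the group means in FPKM (log axis); coloured points passed an adjusted p of 0.05. The 1402 higher and 1799 lower genes lie mostly close to 0, with a tail of strong falls led by Lif.

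Adipocyte genes differed widely in level in both groups. Adipoq, which encodes adiponectin, had 1 read in the 3 alone libraries and 0 in the 3 co-culture libraries, where 3 reads correspond to at most 0.0823 FPKM, and the lipid-droplet gene Plin1 had 12 reads in each group. Pparg, the nuclear receptor that drives adipogenesis, was at 0.688 ± 0.0740 FPKM alone and 0.565 ± 0.0989 in co-culture (262 and 202 reads; adjusted p = 0.337 when low genes were tested). Cebpa was at 0.286 ± 0.0639 and 0.203 ± 0.00947 FPKM (85 and 56 reads; adjusted p = 0.192). Fabp4, the fatty acid binding protein of adipocytes, was at 53.4 ± 3.04 FPKM alone and 58.2 ± 0.740 in co-culture, and its adjusted p of 0.0508 was not past the threshold, although it was 0.0152 without alone replicate 1.

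Of the 8 tested genes on the adipocyte identity list, Plin4 (1.63-fold higher, 2.54 ± 0.201 to 4.15 ± 0.337 FPKM) and Orm1 (1.37-fold higher) rose, and lipoprotein lipase, Lpl (1.19-fold lower, 226 ± 8.34 to 190.5 ± 6.89 FPKM, adjusted p = 0.00135), and Acsl1 (1.16-fold lower) fell. These 8 did not move as a set (camera adjusted p = 0.840), and adjusted over the list alone 3 members were higher and 4 lower. The others of the 22 measured members were below the filter, so the test does not cover them. Among them were Cd36 (3 reads in each group), Cfd (1 in each) and Gpd1 (155 alone and 274 in co-culture). The early adipogenic factors Cebpb (1.46-fold lower, 251 ± 6.86 to 171.6 ± 4.26 FPKM, adjusted p = 3.56e-06) and Cebpd (1.33-fold lower, 122 ± 3.93 to 91.8 ± 4.12 FPKM) fell, as did Klf4 (1.88-fold lower), while Klf6 rose. Over the 16 tested adipogenic transcription factors 4 rose and 5 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.840). That list's median log2 change was 0.034, while its mean was −0.044 and its test pointed down. Among 20 tested regulators that oppose adipogenesis, 3 rose and 7 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.764). Klf2 and the preadipocyte marker Dlk1 (1.21-fold higher, 27.4 ± 1.64 to 33.1 ± 1.38 FPKM) rose, and Twist1 (1.42-fold lower), Ddit3 (1.397-fold lower) and Id3 (1.19-fold lower) fell. The fall of Acsl1, and with it 1 of the 2 lower calls on the identity list, was not called without alone replicate 2 (adjusted p = 0.1002), alone replicate 3 (0.0579), co-culture replicate 1 (0.104) or co-culture replicate 2 (0.0715).

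Inflammatory mediators and cyclic AMP-responsive genes were lower in co-culture. Among the 23 tested inflammatory NF-kB genes 12 fell and 3 rose, the same numbers adjusted over the list alone. Lif, Csf3, Ptgs2 and the neutrophil chemokine Cxcl1 (2.08-fold lower, 384 ± 19.9 to 184 ± 9.30 FPKM) had the smallest p, and the 3 that rose were Nfkbia, the inhibitor of NF-kB (1.58-fold higher, 76.0 ± 2.00 to 119.9 ± 5.65 FPKM), C3 and Vcam1. The list was lower as a set (camera adjusted p = 1.70e-04; adjusted p = 0.309 with an estimated correlation). Among 14 tested cyclic AMP targets 12 fell and 0 rose (13 and 0 adjusted over the list alone), led by Junb (2.29-fold lower, 142.8 ± 3.93 to 62.2 ± 6.73 FPKM), Stc1, Fos and Rgs2 (1.61-fold lower, 196 ± 13.0 to 121.7 ± 9.72 FPKM). This list too was lower as a set (camera adjusted p = 3.16e-08; adjusted p = 0.309 with an estimated correlation). Its members below the filter were not tested. Among them Fosb was at 0.327 FPKM alone and 0.809 in co-culture (138 and 320 reads), and Ppargc1a at 0.738 and 0.752. Nr4a3 was at 0.757 FPKM alone and 0.520 in co-culture, and Crem at 0.395 and 0.353. Of 18 tested glucocorticoid targets 10 fell and 4 rose, the same numbers adjusted over the list alone, with Dusp1 (2.04-fold lower), Gadd45g (1.96-fold lower) and Ddit4 (1.48-fold lower) falling and Nfkbia rising. That list was not called (camera adjusted p = 0.0712), but it passed in 6 of 20 other settings, with an adjusted p of 0.0235 without alone replicate 3.

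Stress-response, glycolytic and cell-cycle genes were modestly lower. Of 28 tested genes of the unfolded protein and integrated stress responses 24 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 4.09e-14; adjusted p = 0.224 with an estimated correlation). The mitochondrial one-carbon enzymes Mthfd2 (1.83-fold lower, 67.4 ± 1.14 to 36.9 ± 2.02 FPKM) and Shmt2 (1.67-fold lower, 47.6 ± 1.44 to 28.5 ± 1.42 FPKM), the serine-synthesis enzyme Psat1 (1.46-fold lower, 159.7 ± 4.598 to 109 ± 3.56 FPKM) and the pseudokinase gene Trib3 (1.57-fold lower) led it. The chaperone gene Hspa5 was 1.32-fold lower. In the hypoxia and glycolysis list 19 of 28 tested genes fell and 2 rose (20 and 3 adjusted over the list alone; camera adjusted p = 5.51e-07; adjusted p = 0.479 with an estimated correlation). Pfkl (1.49-fold lower, 42.0 ± 2.79 to 28.2 ± 0.926 FPKM), Pgam1 (1.32-fold lower), Vegfa (1.29-fold lower, 252 ± 7.03 to 195 ± 2.20 FPKM) and Ddit4 fell, and Ndrg1 and Pfkfb4 rose. The 2 higher members of the list numbered 1 without alone replicate 1 or 2 or co-culture replicate 1 or 3. In the proliferation list 13 of 29 tested genes fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 6.88e-04; adjusted p = 0.309 with an estimated correlation). Ube2c (1.39-fold lower, 19.6 ± 0.633 to 14.1 ± 0.472 FPKM), Mcm2 (1.30-fold), Kif11 (1.42-fold) and Ccnb1 (1.26-fold) fell, and the adjusted p of the list was 0.0607 when only genes with a mean of at least 5 FPKM were tested.

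Lipid genes moved in both directions. Scd1, the stearoyl-CoA desaturase (1.36-fold lower, 203 ± 6.34 to 149.8 ± 11.3 FPKM), and Dgat2 (1.35-fold lower) fell, while Agpat3 (1.21-fold higher) and Dgat1 (1.15-fold higher) rose. These were among 2 higher and 4 lower of 19 tested genes of fatty acid and triglyceride synthesis (3 and 5 adjusted over the list alone; camera adjusted p = 0.764). Of 19 tested genes of lipolysis and fatty acid oxidation, Acadm (1.13-fold higher), Acaa2 (1.17-fold) and Etfdh (1.13-fold) rose and Abhd5 (1.19-fold lower) fell, with the same counts adjusted over the list alone (camera adjusted p = 0.204). The list's members below the filter were not tested. Among them G0s2 was at 1.55 FPKM alone and 0.396 in co-culture (147 and 36 reads). Ppargc1a was at 0.738 and 0.752 FPKM, and Mgll, Cpt1b and Ppara had 7 reads or fewer in each group. In the cholesterol synthesis list 6 of 23 tested genes rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0350; adjusted p = 0.877 with an estimated correlation). Dhcr7 (1.26-fold higher, 5.26 ± 0.342 to 6.64 ± 0.379 FPKM), Hmgcs1 (1.18-fold), Insig1 (1.23-fold) and Mvd (1.22-fold) were the examples. The call on this list was lost without alone replicate 2 (adjusted p = 0.111), alone replicate 3 (0.0515), co-culture replicate 1 (0.0633) or co-culture replicate 3 (0.218). Its 6 higher members numbered 11 without alone replicate 1 and 3 without alone replicate 2, alone replicate 3 or co-culture replicate 3. Its 1 lower member numbered 0 without any library but co-culture replicate 3. In the thermogenic list only Fgf21, Dio2 (1.48-fold lower) and Esrra (1.13-fold lower) could be tested, and all 3 fell. The calls on Etfdh, Mvd and Esrra were each lost without 4 or 5 of the 6 libraries in turn, with adjusted p of 0.108 to 0.124 for Etfdh (alone replicates 2 and 3, co-culture replicates 2 and 3), 0.0566 to 0.132 for Mvd (every library but alone replicate 1) and 0.0821 to 0.171 for Esrra (every library but co-culture replicate 2).

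Genes of the TGF-beta and contractile list moved in both directions. Acta2, smooth-muscle actin, was 1.53-fold higher (185.5 ± 9.35 to 283 ± 6.03 FPKM, adjusted p = 4.37e-06), Myl9 was 1.79-fold higher and Tpm1 was 1.255-fold higher. In that list 7 of 19 tested genes rose and 5 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.204). In the extracellular matrix list 8 of 31 rose and 6 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.451), with Loxl1 (1.35-fold higher) and Timp2 (1.204-fold higher) rising and Col12a1 (1.38-fold lower) and Lamb1 (1.19-fold lower) falling. Of 19 tested insulin signalling genes 3 rose and 7 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.319), with Igf1 1.98-fold higher (1.60 ± 0.00363 to 3.16 ± 0.221 FPKM) and Socs3, Igfbp5 (1.76-fold) and Igfbp4 (1.42-fold) lower. Of 22 tested NRF2 targets 5 rose and 6 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.840), among them the cystine transporter gene Slc7a11 (2.46-fold lower), Srxn1 (1.36-fold lower), G6pdx (1.22-fold lower) and Gstm1 (1.23-fold higher). Of 16 tested p53 and apoptosis genes 6 rose and 7 fell (camera adjusted p = 0.840), with Cdkn1a (1.38-fold lower) and Mdm2 (1.24-fold lower) falling and Sesn1 (1.47-fold higher) and Btg2 (1.24-fold higher) rising. The 8 higher matrix genes numbered 5 without alone replicate 2 or 3 and 4 without co-culture replicate 1 or 3. The 5 higher NRF2 targets numbered 3 without alone replicate 3 or co-culture replicate 2 and 2 without co-culture replicate 3. The 7 lower p53 genes numbered 4 without alone replicate 1, alone replicate 3 or co-culture replicate 1, and the 6 higher ones 3 without co-culture replicate 1. The p53 counts were the same adjusted over the list alone.

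Of 15 tested interferon-response genes 5 rose and 0 fell, including Irf1 (1.195-fold higher), Bst2 (1.21-fold higher), B2m (1.11-fold higher) and Irf9 (1.19-fold higher). The list was not called (camera adjusted p = 0.0962), although its adjusted p was 0.0493 without alone replicate 2, 0.0259 with no filter on low genes and 0.0370 with a filter at 5 FPKM. B2m lost its call without each library but alone replicate 1 (adjusted p 0.0557 to 0.131) and Irf9 without each but alone replicate 2 (0.0680 to 0.117), and the 5 higher members numbered 3 without alone replicate 2 and 2 without alone replicate 3 or any co-culture library. Of 7 tested Wnt targets, Ccnd1 (1.13-fold higher) rose and Myc (1.17-fold lower) fell (camera adjusted p = 0.764). Of 34 tested genes of oxidative phosphorylation 3 rose and 5 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.772), with Cycs (1.29-fold), Uqcrq (1.253-fold), Atp5b (1.12-fold) and Cyc1 (1.11-fold) lower. The 3 higher members of the oxidative phosphorylation list numbered 5 without alone replicate 1, 1 without alone replicate 2, alone replicate 3 or co-culture replicate 1, and 0 without co-culture replicate 3. Transcripts of the mitochondrial genome took 4.995% of reads in co-culture against 4.56% alone (exact permutation p = 0.1), and of its 13 tested genes ND1, ND2 and ND4L rose, 0 fell and 10 were not past the threshold. The interferon and Wnt counts were the same adjusted over the list alone, and 2 Wnt targets were lower without alone replicate 3.

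Endothelial and epithelial markers were near 0 in both groups. No endothelial or epithelial marker reached a mean of 1 FPKM: the highest were Emcn at 0.116 ± 0.0781 alone and 0.141 ± 0.0780 FPKM in co-culture, Pecam1 at 0.0508 ± 0.0200 and 0.0461 ± 0.0321, Krt19 at 0.0318 ± 0.0296 and 0.0348 ± 0.0305, and Grhl2 at 0.0165 ± 0.00577 and 0.0284 ± 0.00679. Of 12 measured macrophage markers only Cd14 (13.8 ± 1.61 and 12.9 ± 1.38 FPKM) and Cd68 (3.75 ± 0.500 and 3.71 ± 0.193) were tested, and neither was past the threshold. The others were below the filter, among them Lyz2 (149 reads alone and 47 in co-culture), Tyrobp (11 and 3) and Fcer1g (10 and 13). The muscle markers Des (1.07 ± 0.208 and 1.36 ± 0.182 FPKM) and Tnnt3 (0.904 ± 0.414 and 1.16 ± 0.0912) were not past it either, although the adjusted p of Tnnt3 was 0.00731 without alone replicate 1. The 3 tested of 13 measured bone and cartilage markers fell. Spp1, osteopontin, went from 560 ± 37.6 to 368 ± 6.87 FPKM (1.52-fold lower), Sox9 was 1.37-fold lower and Runx2 1.21-fold lower. Runx2 lost its call without alone replicate 2 (adjusted p = 0.0683) or 3 (0.0608). The other bone and cartilage markers were below the filter, among them Sp7 (13 reads alone and 4 in co-culture) and Comp (209 and 347). Of 9 tested stromal markers 4 rose and 4 fell, 2 without co-culture replicate 1 (camera adjusted p = 0.840), with Pdgfra (1.16-fold) and Vcam1 (1.14-fold) higher and Alcam (1.29-fold) and Cd44 (1.201-fold) lower, Ly6a at 500.04 ± 20.95 and 563 ± 17.4 FPKM, and Itgb1 at 406 ± 1.73 and 418 ± 4.91 FPKM. The median log2 change of the stromal list was 0.040 and its mean −0.021, and counts of the lists in this paragraph were the same adjusted over the list alone.

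**Figure D3:**
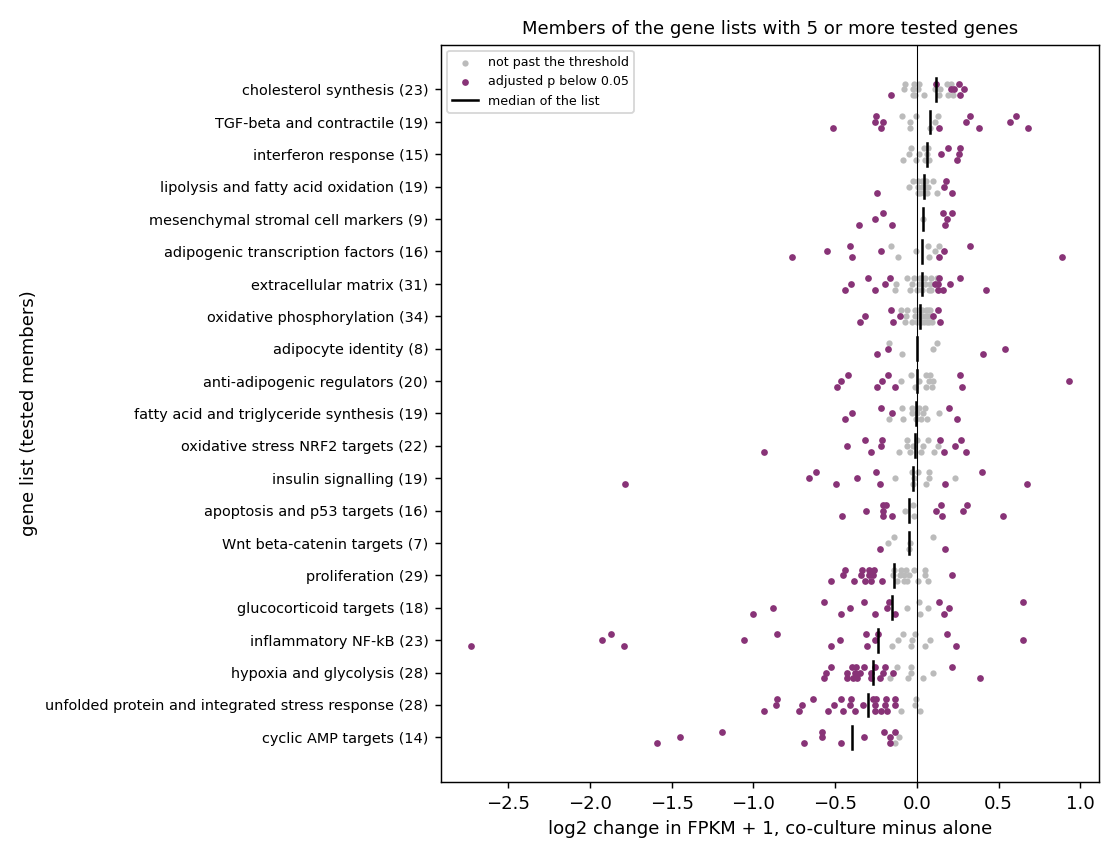
The log2 change in FPKM + 1 (co-culture minus alone) of each tested member of the 21 gene lists with at least 5 tested members; purple points passed an adjusted p of 0.05 and each bar is the median of its list. The cyclic AMP, stress-response, hypoxia and glycolysis, and inflammatory lists have the lowest medians.

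In all, camera with its preset correlation called 6 of 21 lists, 5 lower and 1 higher, and 0 with an estimated correlation, while fry called 8: the 5 lower ones, glucocorticoid targets and insulin signalling (lower) and the TGF-beta and contractile list (higher). Of 4127 annotated terms 35 were called, 11 higher and 24 lower, and 0 with an estimated correlation (lowest adjusted p = 0.994). Amino acid biosynthetic process had the smallest p (22 tested genes, 15 lower and 1 higher, adjusted p = 6.31e-05), and among the higher terms stress fiber (58 genes, 23 higher and 4 lower, adjusted p = 0.0105) and the lysosome (99 genes, 32 higher and 3 lower, adjusted p = 0.0187) were called. Without alone replicate 1 the number of called terms was 102. Each split of the 6 libraries other than alone against co-culture gave 3 to 5 called lists, and these splits gave up to 119 called terms. Those splits mix the groups and keep part of any real difference between them. Their calls therefore cannot show how often camera calls lists that do not differ. The calls did change with the correlation setting, so camera p-values for lists are not to be taken at face value.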

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

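The voom fit, the GC and length correction, the counts of list members without each library and the alternatives for the spread of the libraries were chosen after the data were seen; the others were planned. No called list or called named gene changed direction under the settings run. The count models edgeR and DESeq2 were not run. The plan named edgeR only for a file of raw counts, and the deposited values are FPKM. Limma-voom on the recovered reads was used instead. The number of changed genes was 3201, and 1708 (635 higher, 1073 lower) at an adjusted p below 0.01. Without each library in turn it was 2324 to 3172, with 925 to 1419 higher, where fewer libraries were fitted. Genes higher by a log2 of at least 1 numbered 1, against 8 and 11 with pseudocounts of 0.1 and 0.01, which shrink low genes less, 4 with TPM scaling and 10 with voom; the cause of the last 2 was not tested. The first component held 68.4% of the variance, and 64.2% and 61.4% with the smaller pseudocounts, 60.9% with no filter, 74.2% with a filter at 5 FPKM, 65.1% with TPM scaling, 71.0% after the GC and length correction and 69.5% to 72.4% without each library; the cause was not tested. With an estimated correlation 0 lists and 0 terms were called, and the terms numbered 32 to 102 without each library. The voom fit made 3403 calls, 3013 of them shared with the main test. The replicate number as a block gave 2898 calls, 2818 shared. Deviations of same-numbered libraries correlated at −0.044, 0.109 and −0.083, and alone replicate 1 correlated best with co-culture replicate 3, so the numbers were not taken to pair the samples. Of 103 called named genes 92 kept their call in all settings run and 11 lost it in at least 1, all 11 with no filter on low genes: Fcor, Orm1, Acsl1, Acaa2, Etfdh, Esrra, Insig1, Mvd, B2m, Irf9 and Runx2. Fabp4 passed the threshold in 7 of 18 settings (adjusted p 0.00306 to 0.181). Cholesterol synthesis lost its call in 7 of 20 settings, while glucocorticoid targets gained one in 6 and interferon response in 3. Without each library in turn the lower members numbered 22 to 24 in the stress-response list, 17 to 20 in hypoxia and glycolysis, 11 to 12 in the inflammatory list, 10 to 12 in cyclic AMP targets and 9 to 12 in proliferation. Depth limits Adipoq and Plin1, which had 12 reads or fewer per group, and the simulation did not cover genes that low.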

Other observations

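The tests of immediate-early genes, of cyclic AMP signalling, of oxygen, of amino acids and of blood transcripts were chosen only after the results they concern had been seen, as were the genes named here outside the naming rule. ATF4 targets, among them genes of amino acid synthesis and transport, were mostly lower in co-culture. Of 25 tested ATF4 targets, 14 of them also on a fixed list, 24 fell and 0 rose, with Cth, the cystathionine gamma-lyase, 2.34-fold lower (44.8 ± 2.35 to 19.2 ± 0.471 FPKM, n = 3), and the serine-synthesis genes Phgdh (79.9 ± 2.06 to 48.8 ± 3.54 FPKM) and Psph (9.16 ± 0.154 to 5.86 ± 0.565 FPKM) lower. The amino acid transporter genes Slc7a1 (18.6 ± 1.08 to 10.0 ± 0.808 FPKM) and Slc7a5 (46.9 ± 2.65 to 25.5 ± 3.34 FPKM) and the formate-cycle gene Aldh1l2 (19.4 ± 1.28 to 10.8 ± 0.972 FPKM) also fell, while Sesn2 was at 24.3 ± 0.244 and 24.3 ± 1.01 FPKM.

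Of 18 measured cytoskeletal targets of serum response factor 12 rose and 0 fell. That was 66.7% (exact binomial interval 41.0% to 86.7%, which treats the genes as independent), with a median log2 change of 0.18. The result met the rule set before the targets were looked at. Csrp1 went from 43.5 ± 2.33 to 58.6 ± 0.727 FPKM, Cnn2 from 183.7 ± 5.20 to 242.9 ± 2.49 FPKM and Srf itself from 12.1 ± 0.620 to 15.1 ± 0.257 FPKM (n = 3). That list left out other targets of the same factor. Of 13 tested ones, listed after their values had been seen, 6 rose, among them Acta2, Tagln and Myl9, which raised the question, and Fos, Junb, Ier2, Egr1 and Nr4a1 fell. For that reason, added after the result, whether its targets rose in general stays open.

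The 24 called-lower members of the inflammatory and cyclic AMP lists had a median log2 change of −0.55. A bias from GC content or gene length is argued against: after correction the median was −0.52 and 23 of the 24 were still lower, with a median SE of 0.0578. A drop of immediate-early genes from handling or harvest could not be decided. Of 27 tested immediate-early genes 13 fell, while Klf2, Klf6, Egr3, Dusp5 and Btg2 rose. The lower share, 72.2% of the 18 called, fell short of the share that the rule for this test asked for. An exact binomial interval, added after the share was seen, was 46.5% to 90.3% and included the share asked for. That interval treats the genes as independent, which they are not. In addition, 15 of the 27 are also on a fixed list, and Fos and Junb belong to the pattern itself, so the test is not independent of it. Lower cyclic AMP signalling may contribute, but this stays open. With the members among those 27 immediate-early genes left out, 7 of the remaining 9 cyclic AMP targets fell. Camera on the remaining targets gave p = 1.45e-05, and 0.0547 with an estimated correlation. The 27 may not include every immediate-early gene, so these targets cannot separate lower cyclic AMP signalling from an immediate-early drop. They are also part of the pattern. Whether lower Lif, Il6, Csf3 and Il11 went with lower STAT3 targets stays open. Of 13 tested targets 2 fell, Osmr and Tnfrsf12a, and 0 rose (15.4% lower, exact binomial interval 1.92% to 45.4%, which treats the genes as independent). That share met the rule set beforehand for counting against lower STAT3 targets. Of 12 tested targets that list left out, named after their values had been seen, 10 fell and 1 rose. Those that fell include Socs3, Junb, Fos, Cebpb and Cebpd, all reported above as lower. For that reason, added after the result, the question was left undecided.

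The 43 called-lower members of the hypoxia-glycolysis and stress-response lists had a median log2 change of −0.37, and −0.36 after correction for GC content and length, with 42 still lower. Oxygen used up by the human cells would have raised the hypoxia and glycolysis list, whose median was −0.27 with 19 of 28 lower. Amino acids used up by them would have raised the ATF4 targets, whose median was −0.51; both tests use values that also make up the pattern, and argue only against shortage as its whole cause. What stays open is a biological effect of the human cells, such as a signal or nutrient they add, or a difference between the cultures in density or medium, neither of which was tested.

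Blood-cell transcripts at trace level differed between libraries. Hbb-bs and S100a9 drew attention with 0 reads in co-culture replicate 1, and 10 of the 10 other blood genes, among them Hba-a1, Ngp and Ltf, were lowest in that library (binomial p = 1.65e-08, with genes that share a source not being independent). The most abundant were S100a9 at a mean of 5.86 FPKM and Hbb-bs at 2.23 FPKM, and Lyz2 of this list is also a macrophage marker. With those 10 genes lowest in the same library, reads from another mouse source in the libraries are a candidate explanation, and that source was not identified. Without co-culture replicate 1 the log2 change of Hbb-bs was −1.0005 (adjusted p = 0.0106).

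For each count, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The other splits also mix the groups. Each keeps part of any real group difference in its contrast and puts the rest into the spread within its groups. A low count of changed genes there is thus likely wherever the groups differ. The other splits are therefore not a comparison without a difference. The real split gave 3201 changed genes and 26 by a log2 of at least 1, and 0 was the highest of the others for both, so 1 of 10 splits reached each count. It gave 6 called lists, against 3 to 5 in each of the others, so 1 of 10 splits reached that count. For annotated terms 6 of the 10 splits gave as many as the 35 of the real one, with a highest other of 119.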
